A study of Arabidopsis thaliana with 4 samples.

How the data were processed

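RNA was measured in 4 samples of sorted protoplasts from flowers of ebp1 mutants, 2 of residuum cells (REC) and 2 of secession cells (SEC). Per the labels, plants were grown at 22°C with 16 h of light and 8 h of dark. RNA was extracted with a column kit for small samples and copied to cDNA with a template-switching kit for low input (SMART-Seq v4, 18 amplification cycles). Libraries were then made with TruSeq v2, a kit that does not mark the strand of the RNA. Amplification without molecular identifiers means that reads are not independent molecules, so the counting intervals and the limits for 0 counts cover counting error only.

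Groups and replicate numbers were taken from the sample titles. The genotype labels number the reporter promoter differently in each sample, rising by 1 from QRT2, while the description of the series gives QRT2 for all of them; QRT2 was used. The mutation ebp1 stands in the titles and the description of the series and not in the genotype labels. The reference used for names has 0 genes named SARP1.

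The deposited values are raw counts of reads per gene, whole numbers with 1 file per sample, as the values and the counter's own summary lines show. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, FastQC 0.11.2, Trimmomatic 0.32.3, TopHat2 2.0.9, Picard 1.119, HTSeq 0.6.1 and DESeq2, with the TAIR10 build. The annotation and the strand setting of the counting are not given in the sources used here. The files list 33602 genes, of which 23144 had a count in at least 1 library. Names, products, transcript lengths and overlaps between genes came from the RefSeq annotation of TAIR10.1, matched by locus identifier for 32835 genes. Its build differs in name from that of the files, so no coordinates are given. Genes of the chloroplast and mitochondrial genomes had 0 counts in every library.

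Each file ends with 5 lines that name no gene, and these stayed out of library sizes and tests. The line for records in no gene held 46.81% and 46.82% of all records in the REC libraries and 47.74% and 47.34% in the SEC libraries. Records with more than one alignment made up 7.48%, 7.03%, 5.64% and 5.74% in the same order. Such records are not in the gene counts, so genes with near-identical copies are uncertain. Genes overlapped by one on the other strand are uncertain too, because the library kit does not mark strand.

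Gene counts per library ran from 12191718 to 16102115. At that depth 3 counts, the limit that a count of 0 allows, are 0.246 and 0.209 CPM in the REC libraries and 0.218 and 0.186 CPM in the SEC libraries. The 2 libraries of a group were compared before they were averaged. No files were identical, and both same-group pairs differed by more than sampling noise, with a chi-square per degree of freedom of 5.52 for the REC pair and 74.8 for the SEC pair.

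The comparison was REC minus SEC, with group as the only term. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest) after TMM normalization and filterByExpr, which left 18384 genes. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, and all tests were two-sided. CPM values use the TMM-scaled library sizes. A standard error is the size of the log2 fold change divided by the square root of F. Where the lower group had 3 counts or fewer in all, a named gene is given by its levels or by the ratio of summed counts with an exact 95% interval.

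Before the data were examined, 21 gene lists with 415 members were fixed, for processes of abscission and for cell types that the sort could hold; 406 members matched the reference by identifier and symbol. Lists with 5 or more tested members, 17 in all, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. With the correlation estimated from the data, 0 of the 7 lists called by camera kept the call, and fry, which tests whether a list's genes move on balance one way, called cutin and wax (adjusted p = 0.0269) and senescence (adjusted p = 0.018). No tested gene stood in more than one list. Where the lower group of a list member had 3 counts or fewer, putting it at its bound left the medians printed here as they were.

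The genes named in the report were chosen by a rule also fixed before the data were examined. It takes the 6 largest and 6 smallest log2 fold changes among called genes with a mean of at least 10 CPM and no overlap between the groups. It adds the called members of each list with the smallest p, up to 4 for abscission signalling, wall remodelling, lignin, and cutin and wax, and up to 2 for other lists. QRT2, IDA, HAE, HSL2, PRX72, RBOHD, RBOHF, ADPG2 and any gene named SARP1 or EBP1 are given whatever their p. The rule gave 43 genes. RBCS1A and the genes named only in the closing sections, GAPA, LHB1B2, LHCA4 and members of protein families among them, are additions made after their values were seen.

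The testing steps were checked on simulated counts for the 18384 genes of REC against SEC, drawn from the means and library sizes of the real libraries in 5 runs. The test recovered 12.9% of genes changed 2-fold, 82.3% of those changed 4-fold and 100% of those changed 16-fold. Of 749 calls, 16 were false (2.14%), and 0 had the wrong direction. Those counts held no length trend and had the same spread in both groups, unlike the real pairs. They therefore do not show the false share or the recovery under the unequal spread of these data. A shifted list was called in 5 of 5 runs, and 0 of 78 tests of unshifted lists gave a call. Genes were drawn independently of each other, so these runs cannot show how camera behaves on lists of correlated genes.

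The alternatives were other scalings (RLE and upper quartile), no filter and a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma voom, the replicate number as a block, organelle genes left out, a test against a fold change of 1.5, and each library left out in turn. A correction for transcript length was added after the data were seen. It removes from each library the smooth trend of the log2 ratio to the mean of the 4 libraries on log2 length. On simulated counts for REC against SEC with a length trend in 1 library, it lowered the rank correlation of fold change and length in unchanged genes from 0.524 to 0.005. In those counts 19 of 206 calls were false without the correction and 14 of 208 with it. They were drawn with a smaller spread than that fitted to the real libraries, so these shares cannot be set beside those of the first simulation. Families, overlaps and figures were computed with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Reads were not analysed here.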

Results

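Floral organs of Arabidopsis thaliana are shed at the abscission zone, where adjoining cell layers part. The residuum cells (RECs) stay on the receptacle side of the break and the secession cells (SECs) leave with the detached organ. Both kinds of cell were sorted as protoplasts from ebp1 mutants in the Col-0 background by fluorescence from a nuclear GFP reporter under the QRT2 promoter, which is active in abscission zone cells. The data are polyA RNA-seq counts per gene for 4 libraries, 2 of RECs and 2 of SECs. Counts in genes came to 12191718 and 14338470 in the REC libraries and to 13737549 and 16102115 in the SEC libraries. The REC libraries had 21295 and 21210 genes with a count, and the SEC libraries 19634 and 20416. The design gives one comparison, which asks how the transcriptomes of the cells on either side of the break differ in this mutant. No library of wild-type cells is part of it, so it does not show what the mutation changes. Values are mean normalised counts (CPM, relative to the TMM-scaled library size) ± SD over n = 2 libraries, and log2 fold changes are REC minus SEC, with the standard error (SE) and adjusted p of edgeR's quasi-likelihood test. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

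The labels give no locus for ebp1 or for SARP1, the RNA-binding protein named in the title of the series. The reference names no gene SARP1, and the gene to which it gives EBP1 as a synonym is AT3G51800 (symbol ATG2). ATG2 was read in all 4 libraries, at 91.4 and 92.8 CPM in RECs and 83 and 62.5 CPM in SECs (log2 fold change 0.34, SE 0.23, adjusted p = 0.432 by edgeR). Without SEC replicate 1 its log2 fold change was 0.56 and past the threshold, but the REC pair alone then sets the spread. Whether it is the mutated locus is not stated, and these levels do not check the genotype. QRT2, a polygalacturonase gene whose promoter drives the sorting reporter, stood at 530 ± 53.4 CPM in RECs and 577 ± 166 CPM in SECs. Its log2 fold change was −0.12 (SE 0.24, adjusted p = 0.807). It turned to 0.003 without REC replicate 1 and to 0.22 without SEC replicate 2. Without SEC replicate 1 it was −0.39 and past the threshold, again with the spread of the REC pair alone.

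Of 18384 genes tested, 91 were higher in RECs and 400 were higher in SECs at an adjusted p under 0.05. The strongest in RECs among genes averaging 10 CPM or more was DIN11 (AT3G49620), an oxygenase gene induced by darkness in leaves. It had 1007 counts in the REC libraries and 1 in the SEC libraries, a ratio of 1040 with a counting interval of 186 to 41000. RBCS2B and CA2, for the small subunit of Rubisco and a carbonic anhydrase, were 36-fold and 30.9-fold higher in RECs. AT4G22485, for a lipid-transfer-like protein, had 63 ± 4.1 CPM in RECs and 1.97 ± 1.48 CPM in SECs. AT4G12870, for a thiol reductase of the GILT family, had 56.9 ± 6.48 and 2.12 ± 1.81 CPM. AT5G15780, for an extensin-like protein, had 40.4 and 13.8 CPM in the REC libraries against 0 and 0.257 CPM in the SEC libraries. In SECs, the laccase gene LAC7 had 699 counts against 2 in RECs, a ratio of 340 with a counting interval of 93.7 to 2810. GSTU9, a glutathione S-transferase gene, was 67.4-fold higher in SECs. GPAT5, an acyltransferase gene of suberin synthesis, was 49.2-fold higher and CCOAMT (AT1G67980), a caffeoyl-CoA methyltransferase gene, 36.2-fold higher. The unnamed genes AT2G31345 and AT4G05018 had 39.2 and 11.2 CPM and 38.7 and 14.1 CPM in the SEC libraries, and under 1 CPM in each REC library. AT2G31345 lies wholly within a gene on the opposite strand, which had 118 and 139 counts in RECs and 47 and 63 in SECs. AT2G31345 had 3 and 7 counts in RECs and 508 and 174 in SECs, so it did not follow that gene. Without strand its reads stay uncertain.

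All 491 called genes had both libraries of one group above both of the other, as had 10658 of all the genes tested. A fold change over 4 was fitted for 49 of the genes higher in RECs and 230 of those higher in SECs. In 17 of the called genes the lower group had 3 counts or fewer, so the fitted size is then no bound. The smallest adjusted p was 0.0267 with 2 residual degrees of freedom, and at an unadjusted p under 0.05 there were 1740 genes higher in RECs and 2591 higher in SECs. RECs took 18.5% of the calls. Their share was 32.6% by DESeq2, with 763 and 1574 calls, and 34.7% with the transcript length trend of each library removed, with 896 and 1683 calls. Without REC replicate 1 there were 28 and 86 calls, and without REC replicate 2 there were 76 and 248. Leaving out SEC replicate 1 gave 3557 and 3815 calls and leaving out SEC replicate 2 gave 5630 and 4991, since the spread is then estimated from the REC pair alone. Leaving out a REC library leaves the SEC pair, which differs far more within itself, to set the spread. A call lost in such a fit therefore does not show that it rested on the library left out. Several of the top genes moved by over 1.5 times with 1 library. Without SEC replicate 1 the log2 fold change was −4.42 for CCOAMT, −5.16 for GSTU9, −4.93 for AT2G31345, −4.99 for AT4G05018, 4.38 for AT4G22485 and 6.08 for AT4G12870. Without SEC replicate 2 it was −6.72 for AT2G31345, 6.09 for AT4G22485 and 4.07 for AT4G12870, and without REC replicate 2 it was −6.26 for GPAT5 and −5.19 for AT4G05018, which was −6.94 without REC replicate 1. For AT5G15780 it ran from 6.60 without REC replicate 1 to 11.52 without SEC replicate 2, where the remaining SEC library had 0 counts. LAC7, at −8.19 with all libraries, was −7.16 without REC replicate 2 and −11.43 without REC replicate 1, and DIN11, at 9.70, was 8.73 without SEC replicate 2 and 12.04 without SEC replicate 1; the last value of each is against a library with 0 counts. These genes kept an adjusted p under 0.05 in each of those fits, but limma voom ended the calls of AT2G31345 (adjusted p = 0.214), AT5G15780 (0.193), AT4G05018 (0.152), GSTU9 (0.151) and LAC7 (0.0955).

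The genes of abscission signalling did not shift together, and those that differed did so in both directions. IDA, the peptide ligand that triggers organ separation, was 33.8-fold higher in SECs, with 0.471 and 0.867 CPM in the REC libraries and 32.5 and 13.9 CPM in the SEC libraries (log2 fold change −5.08, SE 0.63, adjusted p = 0.0341). BP (KNAT1), a homeobox gene that restrains abscission, was 3.62-fold higher in SECs, at 1779 ± 204 CPM against 492 ± 22.7 CPM (log2 fold change −1.86, SE 0.16). KNAT6, a homeobox gene that acts in the opposite sense, was 4.22-fold higher in RECs, at 51.1 ± 4.23 CPM against 12.1 ± 1.3 CPM (log2 fold change 2.08, SE 0.25). The receptor kinase genes for the IDA peptide did not pass the test. HAE had 440 and 460 CPM in RECs and 160 and 355 CPM in SECs (log2 fold change 0.80, SE 0.38, adjusted p = 0.283), and HSL2 had 106 and 143 CPM against 68.3 and 127 CPM (log2 fold change 0.36, SE 0.35, adjusted p = 0.597). Of 30 tested members of the list, 1 was higher in RECs, 2 were higher in SECs and 27 did not pass. Adjusted over the list alone, 2 were higher in RECs and 7 in SECs. The median log2 fold change was −0.04, and camera did not place the list apart from other genes (adjusted p = 0.53). HAE and HSL2 have transcripts of 3710 and 3229 nt, and SEC replicate 1 was low in long transcripts. Without SEC replicate 2 their log2 fold changes were 1.502 and 0.88, and without SEC replicate 1 they were 0.34 and −0.02. All but the last were past the threshold, with the spread set by the REC pair alone. With the length trend removed HAE was past the threshold at 0.63 (adjusted p = 0.0286). The transcript of IDA is short, at 865 nt, and its log2 ratio of SEC replicate 1 to SEC replicate 2 was 1.19. IDA was −4.34 without SEC replicate 1 and missed the threshold by limma voom (adjusted p = 0.113), and KNAT6 missed it without either REC library (adjusted p = 0.114 and 0.0803).

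**Figure D1:**
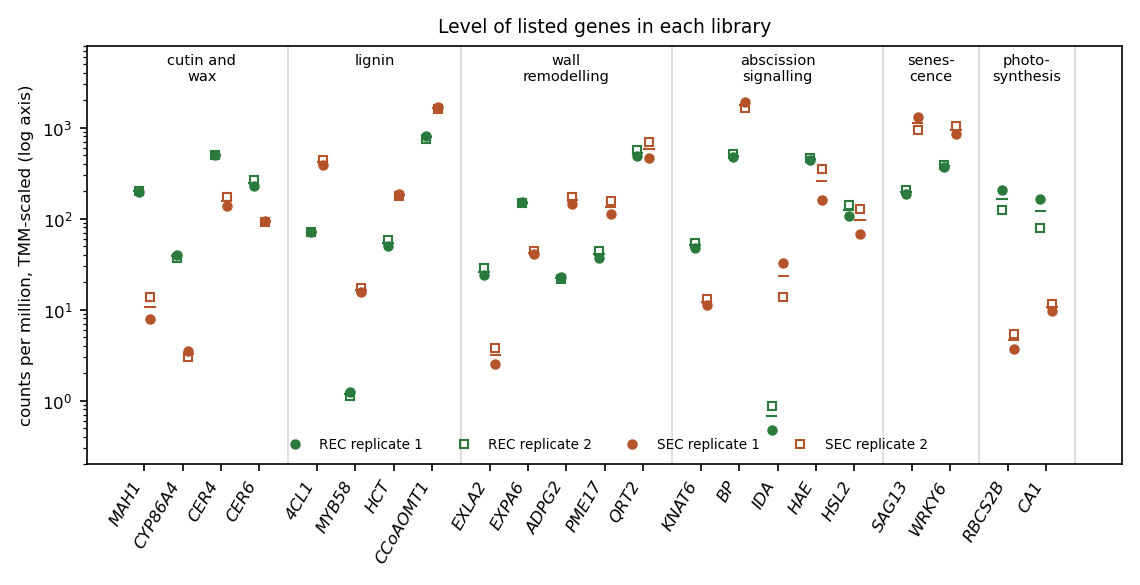
Level of 22 genes from 6 lists in each library, in CPM on a log axis; green points are REC libraries, brown points SEC libraries, filled circles replicate 1, open squares replicate 2, and short lines the group means. IDA, ADPG2 and the lignin genes shown lie higher in both SEC libraries, MAH1, CYP86A4 and RBCS2B lie higher in both REC libraries, and the REC and SEC points of QRT2 overlap.

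Genes that remodel the cell wall also divided between the sides. ADPG2, a polygalacturonase gene of organ separation, was 7.11-fold higher in SECs, at 159 ± 17.2 CPM against 22.3 ± 0.624 CPM (log2 fold change −2.83, SE 0.22, adjusted p = 0.0267). PME17 (AT2G45220), a pectin methylesterase gene, was 3.29-fold higher in SECs. The expansin genes EXLA2 and EXPA6, whose products loosen walls, were 8.23-fold and 3.53-fold higher in RECs, with EXPA6 at 149 ± 1.75 CPM against 42.4 ± 1.73 CPM. Of 28 tested members, 2 were higher in RECs, 2 were higher in SECs and 24 did not pass. The test found 5 higher in RECs and 6 in SECs when adjusted over the list alone. The list did not stand apart by camera (median log2 fold change 0.30, adjusted p = 0.53). Calls for PME17 and EXPA6 were lost without REC replicate 1 and without REC replicate 2, where the SEC pair alone sets the spread. PME17 also missed the threshold with upper-quartile normalization (adjusted p = 0.0502).

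Of 35 matched lignin genes, 21 could be tested. Members too low to test included LAC4, LAC11, LAC17, MYB46, MYB83, NST1, NST2 and NST3. Of the 21 tested lignin genes, 8 were higher in SECs, none was higher in RECs and 13 did not pass. Among those that did not pass were the peroxidase genes PRX52 and PRX71 (log2 fold change −0.10 and −0.50, adjusted p = 0.789 and 0.396 by edgeR). The list was shifted toward SECs by camera at the preset correlation (median log2 fold change −1.08, adjusted p = 6.4e-07), and not with an estimated correlation (adjusted p = 0.413) or by fry (adjusted p = 0.0513). When adjusted over the list alone, 15 were higher in SECs and 0 in RECs. 4CL1, which joins hydroxycinnamic acids to coenzyme A, was 5.78-fold higher in SECs, at 414 ± 40.2 CPM against 71.7 ± 0.397 CPM (log2 fold change −2.53, SE 0.19, adjusted p = 0.0267). HCT and CCoAOMT1, which act later in the pathway, were 3.34-fold and 2.09-fold higher. MYB58, a regulator of lignin genes, had 15.7 and 17.1 CPM in SECs and 1.26 and 1.13 CPM in RECs. MYB58 is covered over its whole length by AT1G16489 on the opposite strand, which had 8 and 11 counts in RECs and 168 and 244 in SECs where MYB58 had 16 and 17, and 204 and 266. Without strand the reads cannot be assigned to one of them. The peroxidase gene PRX72 (AT5G66390) had 0 counts in all 4 libraries, of 56369852 counts in genes, which allows up to 0.0532 CPM. RBOHD and RBOHF, NADPH oxidase genes that supply the peroxide for lignin polymerisation, did not pass the test. RBOHD had 220 ± 6.44 CPM in RECs and 237 ± 95.5 CPM in SECs (log2 fold change −0.11, adjusted p = 0.868), and RBOHF had 147 ± 3.37 and 126 ± 76.2 CPM (log2 fold change 0.22, adjusted p = 0.805). Both have long transcripts, of 3603 and 3994 nt, and both turned with the SEC library used. Without SEC replicate 1 RBOHD was −0.47 and RBOHF −0.29, and without SEC replicate 2 they were 0.39 and 1.03. Each of these passed the threshold, in opposite directions, with the spread set by the REC pair alone. Calls for HCT and CCoAOMT1 were lost without REC replicate 1 (adjusted p = 0.304 and 0.233) and without REC replicate 2 (0.119 and 0.244), that for MYB58 without REC replicate 1 (0.0533), and that for CCoAOMT1 with upper-quartile normalization (0.0502).

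Of 34 tested cutin and wax genes, 5 were higher in RECs, none was higher in SECs and 29 did not pass. Camera placed the list higher in RECs at the preset correlation (median log2 fold change 0.59, adjusted p = 6.4e-05), and not with an estimated correlation (adjusted p = 0.413). There were 11 higher in RECs and 0 in SECs adjusted over the list alone. MAH1 (CYP96A15), the alkane hydroxylase of wax synthesis, was 18.5-fold higher in RECs, at 198 and 202 CPM against 7.95 and 13.6 CPM (log2 fold change 4.21, SE 0.33, adjusted p = 0.0267). CYP86A4, a fatty acid hydroxylase gene of cutin synthesis, was 11.7-fold higher. CER4 and CER6 (KCS6), which make wax alcohols and very long chain fatty acids, were 3.17-fold and 2.63-fold higher. Calls for CER4 and CER6 were lost without REC replicate 1 (adjusted p = 0.116 and 0.231), and that for CER6 also without REC replicate 2 (0.354). The suberin list, a related polyester pathway, did not stand apart (adjusted p = 0.53). Of its 13 tested members GPAT5 was higher in SECs and 12 did not pass; adjusted over the list alone, 1 was higher in RECs and 3 in SECs. The list of epidermal identity did not stand apart either (13 tested, median log2 fold change 0.29, mean 0.03, adjusted p = 0.673), and fry gave it the opposite direction with an adjusted p of 0.992. Its member PDF2, a homeobox gene of the epidermis, was 3.47-fold higher in SECs, at 30.9 ± 0.944 CPM against 8.88 ± 1.43 CPM, the only member also called when adjusted over the list alone. That call was lost without REC replicate 1 (adjusted p = 0.3), without REC replicate 2 (0.399) and with upper-quartile normalization (0.0524).

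**Figure D2:**
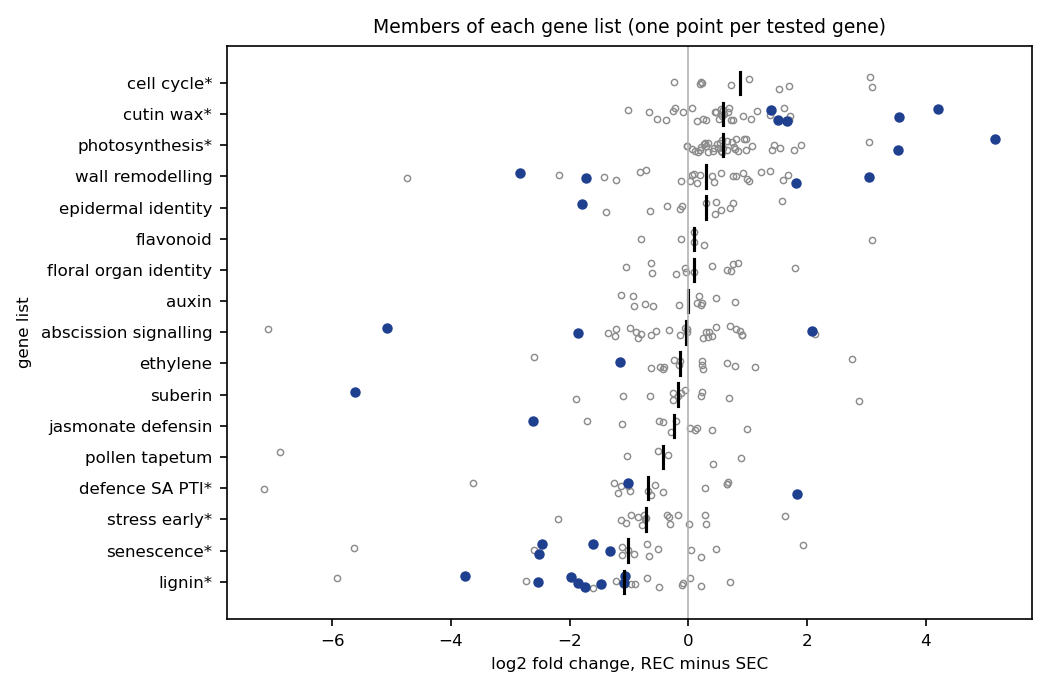
Log2 fold change, REC minus SEC, of every tested member of 17 gene lists; filled points passed the edgeR test, open points did not, black bars are list medians, and a star marks lists that camera called with the preset correlation. The called members of lignin lie left of 0 and those of cutin and wax right of 0, with list medians of −1.08 and 0.59.

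Of 40 tested photosynthesis genes, RBCS2B and CA1 were higher in RECs, by 36-fold and 11.6-fold, and 38 did not pass the test. The median log2 fold change of the list was 0.58, and 38 members had a positive value. RBCS2B had 206 and 126 CPM in RECs and 3.71 and 5.46 CPM in SECs. CA1, a chloroplast carbonic anhydrase gene, had 166 and 79.1 CPM against 9.57 and 11.6 CPM (log2 fold change 3.53, SE 0.43, adjusted p = 0.0341), and 2.93 without REC replicate 1. RBCS1A, the most abundant Rubisco small subunit gene of the list, stood at 1510 CPM in RECs and 1529 CPM in SECs. The RBCS and CAB genes have near-identical copies, so their separate levels are uncertain. Adjusted over the list alone, 20 were higher in RECs and 0 in SECs (camera adjusted p = 3.74e-07, and adjusted p = 0.66 with an estimated correlation). The cell cycle list was also called higher in RECs (10 tested, median log2 fold change 0.87, adjusted p = 0.0133, and adjusted p = 0.413 with an estimated correlation). None of its members passed alone, over all genes or over the list alone, and without SEC replicate 2 the list's adjusted p was 0.259. Among markers of other cell types, the floral organ identity list (13 tested, adjusted p = 0.53) and the pollen and tapetum list (6 tested, adjusted p = 0.585) did not stand apart. Adjusted over the list alone, 2 floral organ identity members were higher in RECs and 0 pollen and tapetum members differed. Markers of nectary, phloem, xylem and of guard and myrosin cells were mostly too low to test, with 2, 3, 4 and 2 members tested. Adjusted over each list alone, 1 nectary and 1 xylem member were higher in SECs and 1 guard or myrosin cell member was higher in RECs. Of these, MC9, a metacaspase gene of xylem cell death, was called over all genes and was 20.3-fold higher in SECs, at 48.6 and 80.9 CPM against 4.55 and 1.87 CPM. Its log2 fold change of −4.34 was −5.09 without REC replicate 1.

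Of 17 tested senescence genes, 4 were higher in SECs, none was higher in RECs and 13 did not pass. By camera the list lay higher in SECs at the preset correlation (median log2 fold change −1.02, adjusted p = 0.000372), and not with an estimated correlation (adjusted p = 0.413). There were 8 higher in SECs and 0 in RECs adjusted over the list alone. SAG13, a senescence-associated dehydrogenase gene, was 5.71-fold higher, at 1128 ± 276 CPM against 198 ± 14.9 CPM (log2 fold change −2.51, SE 0.23, adjusted p = 0.0274). WRKY6, a transcription factor gene of senescence and defence, was 2.48-fold higher, and its call was lost without REC replicate 1 (adjusted p = 0.245) and without REC replicate 2 (0.116).

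The lists for salicylic acid and pattern-triggered defence and for early stress were lower in RECs by camera, each with an adjusted p of 0.0414. With an estimated correlation the adjusted p was 0.508 and 0.66. Of 17 tested defence members, WRKY33 was 2.02-fold higher in SECs (log2 fold change −1.01, SE 0.17, adjusted p = 0.0499), and WRKY70, which acts in salicylic acid responses, was 3.54-fold higher in RECs. In this list 1 was higher in RECs and 5 in SECs adjusted over the list alone. Calls for WRKY33 and WRKY70 were lost without REC replicate 1 (adjusted p = 0.608 and 0.175) and without REC replicate 2 (0.348 and 0.151), and WRKY33 also missed with upper-quartile normalization (0.0633). None of the 17 early stress members, markers of protoplast handling among them, passed over all genes, and 2 were higher in SECs adjusted over the list alone. The defence list lost its call without REC replicate 1 (adjusted p = 0.109) and without SEC replicate 1 (0.127). The stress list lost it without REC replicate 1 (0.102), REC replicate 2 (0.129) or SEC replicate 1 (0.133), and with the length trend removed (0.0574).

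Hormone lists did not stand apart by camera, with an adjusted p of 0.37 for jasmonate and defensins (12 tested), 0.655 for auxin (12 tested) and 0.749 for ethylene (16 tested). AOC1, an allene oxide cyclase gene of jasmonate synthesis, was 6.17-fold higher in SECs, at 110.2 ± 30.9 CPM against 17.8 ± 0.453 CPM. ACO4 (EFE), which makes ethylene, was 2.22-fold higher in SECs, at 2273 ± 170 CPM against 1023 ± 12.5 CPM. Adjusted over the list alone, 2 jasmonate genes were higher in SECs, 1 ethylene gene was higher in each group, and 0 auxin genes differed. AOC1 lost its call without REC replicate 1 (adjusted p = 0.0878), as did ACO4 (0.165), which also lost it without REC replicate 2 (0.077). The flavonoid list (6 tested) did not stand apart (adjusted p = 0.585), with 0 members called over all genes and 1 higher in RECs adjusted over the list alone.

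The SEC libraries differed from each other far more than the REC libraries did. A chi-square of their counts per degree of freedom was 74.8 for the SEC pair and 5.52 for the REC pair, against 87.9 to 127 for pairs across the groups. By correlation of log2 CPM across genes, SEC replicate 2 was no closer to SEC replicate 1 (0.865) than to REC replicates 1 and 2 (0.885 and 0.884). Among genes averaging 5 CPM or more, it correlated at 0.889 with SEC replicate 1 and 0.885 with REC replicate 1. With the length trend removed these values were 0.927 and 0.885. The difference within the SEC pair followed transcript length. From the shortest to the longest sixth of genes, the median log2 ratio of SEC replicate 1 to SEC replicate 2 went from 0.65 to −0.87, and in the REC pair from 0.06 to −0.04. Among the lists, the median log2 ratio of SEC replicate 1 to SEC replicate 2 was −0.75 for epidermal identity, with a median transcript of 3286 nt, and 0.51 for early stress, with 1385 nt. It was −0.36 for lignin, −0.05 for cutin and wax, 0.09 for photosynthesis and 0.17 for senescence. Of the genes strongest in SECs, AT2G31345, AT4G05018, GSTU9 and CCOAMT have short transcripts, of 569 to 1169 nt. Their log2 ratios of SEC replicate 1 to SEC replicate 2 ran from 1.26 to 1.77, so their fold changes lean on SEC replicate 1. The ratio was 0.15 for GPAT5 (2000 nt) and −0.84 for LAC7 (2501 nt).

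**Figure D3:**
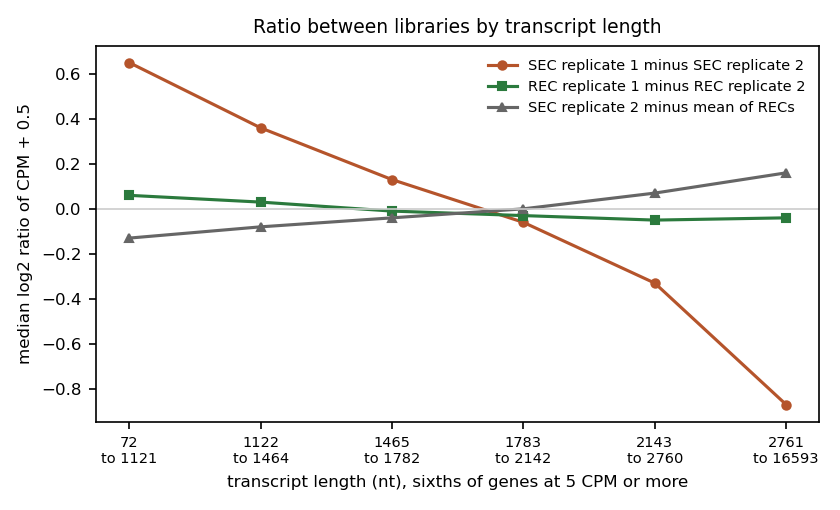
Median log2 ratio of CPM + 0.5 between libraries for 6 groups of genes ordered by transcript length in nt; brown circles set SEC replicate 1 against SEC replicate 2, green squares REC replicate 1 against REC replicate 2, and grey triangles SEC replicate 2 against the mean of the RECs. The brown line falls from 0.65 to −0.87 and the green line stays between 0.06 and −0.05.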

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

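The test of opposite-strand pairs was chosen after the share of records in no gene had been seen. These records are a signal outside the gene counts, and there is no control library to set them against. They made up 46.81% of all records in REC replicate 1 and 46.82% in REC replicate 2. In SEC replicate 1 they made up 47.74% and in SEC replicate 2 47.34%. Wilson 95% intervals are narrow, from 46.787% to 46.825% in REC replicate 1, and cover counting error only. For each count in a gene there were 1.032, 1.023, 1.034 and 1.019 records in no gene, in the order of the libraries above.

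A ratio so close to 1 in every library is what counting by strand would give for reads that carry no strand, since reads of the wrong orientation are then left without a gene. Where genes on opposite strands cover each other, such counting would give both about the same count. In 52 pairs that overlap over 80% or more of both genes' exons, with enough counts to compare, the median ratio of the lower to the higher count was 0.892 (quartiles 0.793 and 0.948). With partners shuffled 1000 times the median was 0.316 and the highest 0.496. Counting by strand is thus a candidate explanation that passed a test that could have failed, though the setting itself is not given in the sources used here. It would lower all genes alike and leave fold changes in place, except in genes with an overlap: 21 of the 491 called genes are overlapped over more than 50% of their exons. No biological explanation was tested, since the share is nearly the same in both groups.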

How the results depend on the processing

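The length correction and its combination with the block were chosen after seeing the data; all other alternatives were set beforehand. Of 588 values, for 42 tested named genes under 14 alternatives, 522 kept their direction and side of the threshold, 53 lost the call, 8 gained one and 5 reversed. The cause was not tested. Among the 522 are 42 values from leaving out organelle genes, which had 0 counts and so could move nothing. Fits without a SEC library take their spread from the REC pair and were unlikely to lose a call. The tally therefore overstates how firmly the values hold. Reversed were log2 fold changes of genes not called with all 4 libraries. RBOHF was −0.29 and HSL2 −0.02 without SEC replicate 1, and 1.03 and 0.88 without SEC replicate 2. RBOHD was −0.47 and QRT2 −0.39 without SEC replicate 1, and 0.39 and 0.22 without SEC replicate 2. QRT2 was 0.003 without REC replicate 1.

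Counts of genes higher in RECs and in SECs, 91 and 400 with all settings as reported, moved as follows. Upper-quartile normalization gave 254 in SECs, all among the 400. There were 280 and 836 without a filter and 176 and 654 with the stricter filter. DESeq2 gave 763 and 1574, and testing against a fold change of 1.5 gave 27 and 107. With the length trend removed there were 896 and 1683. Leaving out 1 library gave 28 to 5630 and 86 to 4991. The cause of these moves was not tested, except that leaving out a library leaves the pair of the other group to set the spread. The lone library of a group is then assumed to vary like the other group. Without SEC replicate 1 or 2, with DESeq2, without a filter, under the block and with the length trend removed, all 491 called genes were among the calls. RLE and limma voom stayed within 1.5 times, and leaving out organelle genes moved nothing, as they had 0 counts.

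The samples share only a replicate number. The deviations of REC replicate 1 and SEC replicate 1 from their group means correlated at 0.038 across genes. With 2 libraries per group, the replicate 2 pair repeats that value by construction. It does not show a pairing. The replicate block gave 526 and 1161 calls, and 688 and 1476 with the length trend removed as well. Of the 7 lists called by camera, 5 were called under the block (the defence and early stress lists each had an adjusted p of 0.0541), 5 to 6 with 1 library left out, 6 with the stricter filter, which left cell cycle too few members, 2 by fry and 0 with an estimated correlation. Lignin, cutin and wax, photosynthesis and senescence were called by camera with each library left out.

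Limma voom ended the calls of IDA, AT2G31345, LAC7, AT4G05018, AT5G15780 and GSTU9, and testing against a fold change of 1.5 ended 18. In simulated data with the same spread in both groups, 12.9% of 2-fold changes were recovered, so small changes can be missed.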

Other observations

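Among the 491 called genes, 30 protein families were counted by words in the product names, with Fisher's exact test against the tested genes with a product and Benjamini-Hochberg adjustment per direction. The families were chosen after the called genes had been seen, and word patterns that had taken in unrelated proteins were corrected after a first count, so the result is a description of these genes. In SECs 7 families were over-represented. Glutathione S-transferases, which conjugate toxic compounds, led with 12 of 40 tested genes where 0.9 are expected (adjusted p = 8.92e-10). GSTF6 had 386 and 155 CPM in the SEC libraries against 12.8 ± 2.15 CPM in RECs, and GSTU1 had 207 and 97.7 CPM against 16.5 ± 2.39 CPM, so the size of both differences depends on the SEC library. GSTU19 was 2.07-fold higher in SECs (2769 ± 268 CPM against 1339 ± 58.6 CPM). WRKY factors had 7 of 51 called (adjusted p = 0.00164), among them WRKY30 (9.46-fold higher in SECs), WRKY25 (4.83-fold) and WRKY15 (2.24-fold). NAC factors had 5 of 60 (adjusted p = 0.0413), among them NAC047 (5.64-fold) and NAC053 (2.93-fold). MYB and homeodomain-like factors had 10 of 142 (adjusted p = 0.0108), with MYB108 5.32-fold and MYB63, a lignin regulator, 3.64-fold higher in SECs. Cytochromes P450 had 8 of 116 (adjusted p = 0.0228), with CYP81D8 4.07-fold higher (1436 ± 153 CPM against 353 ± 6.44 CPM). Peroxidases had 4 of 35 (adjusted p = 0.0336), with PRXCB 2.71-fold higher, and berberine-bridge-like oxidases had 3 of 15 (adjusted p = 0.0228). Several of these genes lie beside near-identical neighbours, such as GSTF6 and GSTF7, so their separate levels are uncertain. These names were chosen after their values were seen, and the family counts were not run with a library left out.

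In RECs 3 families were over-represented. GDSL lipases, a family with roles in cutin assembly, had 4 of 45 tested genes called where 0.2 are expected (adjusted p = 0.00227). AT3G16370 was 4.32-fold higher in RECs, AT4G28780 3.66-fold, AT1G29660 3.33-fold and AT1G29670 2.02-fold (2314 ± 26.6 CPM against 1148 ± 161 CPM). Expansins had 2 of 14 (adjusted p = 0.0327), EXPA6 and EXLA2. Laccases and multicopper oxidases had 2 of 20 (adjusted p = 0.0446), with sks17 18.5-fold and SKS6 4.31-fold higher. The same family had 2 of 20 called in SECs, LAC7 and sks13 (adjusted p = 0.173), so it holds genes of both directions.

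Of the tests weighed from here on, those of length as the whole cause, depth, near-identical copies and length for photosynthesis were set before their results were seen; the others were chosen after. SEC replicate 1 stands apart: on the first principal component (68.9% of the variance) it lies at 120.6, SEC replicate 2 at 21.1 and the RECs at −70.1 and −71.5, while on the second (25.4%) SEC replicate 2 is the one apart, at −82.2 against 20.1 to 39.4. The median log2 ratio of the SEC pair falls by 1.52 from the shortest to the longest sixth of genes and that of the REC pair by 0.1, so loss of long transcripts in SEC replicate 1 is a candidate explanation for part of it. It is not the whole, since with the length trend removed the correlation of the pair across genes is 0.927 against 0.987 in the REC pair, and thinning to one total, which would remove an effect of depth, left it at 0.889, its value as deposited. REC material in SEC replicate 2 would have to make up a share of 0.56 (quartiles 0.37 and 0.69) to explain 406 genes high in SEC replicate 1. For 167 genes at least 4-fold lower in SEC replicate 1 than in RECs, the median ratio of SEC replicate 2 to the REC mean was 0.57 (quartiles 0.27 and 0.82). Of these genes 31.7% lie, in SEC replicate 2, under 0.37 of the lower REC library. That bound is the lower quartile of the needed shares, so some genes would fall under it even if the shares matched. Both sets of genes were also picked by their level in SEC replicate 1, without the length correction. Against the REC mean, its median log2 ratio ran from 0.52 in the shortest sixth of genes to −0.72 in the longest. Shifts of that library alone would place SEC replicate 2 nearer the RECs with no REC material. The values of 0.56 and 0.57 therefore do not measure REC material, and the test cannot decide on it as the whole cause. REC material as a part or the whole of the cause stays open, as does an untested difference between the organs collected. Of the 167 genes 18.0% lie below 0.2 of the REC level, between the bounds of under 5% and of 20% set for that test. The test with 31.7% was added knowing this.

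The photosynthesis list was called higher in RECs by camera at the preset correlation, and not with an estimated correlation, which was 0.566 (adjusted p = 0.66). Near-identical copies alone do not account for the list's median. Without the RBCS, CAB, LHB1B and LHCB2 copies, 30 genes remain, with a median log2 fold change of 0.56. Their camera p was 5.72e-06 at the preset correlation, under the bound of 0.05 set for that test. The 30 genes were not tested with an estimated correlation, so this p has the same limit as the list's call. Length is argued against, since the median with the length trend removed is 0.64, and it was 0.58 before. A larger share of green cells in the REC sorts could raise all these genes, and 38 of 40 had a positive log2 fold change. Every tested member was also higher in REC replicate 1 than in REC replicate 2. The list summed to 21100 and 17200 CPM in these libraries, and to 13900 and 12900 CPM in SEC replicates 1 and 2. The list thus also moved together within the REC pair, for a cause not tested. Abundant members differed in its size. RBCS1A, the most abundant RBCS gene of the list and one of the near-identical copies, had −0.018 (SE 0.25), and GAPA had 0.26 (SE 0.14). LHB1B2, also one of the copies, had 0.83 (SE 0.18), and LHCA4 had 0.78 (SE 0.17). The sort by the QRT2 reporter would remove green cells that lack it, how far was not tested, and such single genes do not decide, so greener cells of the receptacle and an admixture cannot be told apart.

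In SEC replicate 1, 10 genes lay under 1 CPM while all other libraries had 10 CPM or more, with a median transcript of 3196 nt; no other library had such a gene. AT1G79245, a transcribed pseudogene, took 1.17% of the gene counts of SEC replicate 2.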
